A study of Xenopus laevis with 6 samples.

How the data were processed

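Total RNA from fixed and dissected 8-cell *Xenopus laevis* embryos was amplified, labelled with biotin and hybridized to 6 one-colour short-oligonucleotide arrays, 3 of animal blastomeres and 3 of the vegetal-most part of vegetal blastomeres, per the labels' protocols. The deposited table holds 1 linear intensity per probe set and array, made by the authors with GCOS, the array maker's software, per the submitters' processing notes. Its version, background correction and settings are not given in the sources used here. The deposited intensities had a 2% trimmed mean of 150.0 on each of the 6 arrays, which shows that each array had been scaled to 1 common target, so they were used without further scaling. No detection calls and no scanner files were used here. Replicates were not pooled, and no 2 arrays were copies of one another.

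Of 32635 probe sets, 96 were control probe sets and stayed out of the tests. Gene names came from the platform annotation supplied for the array, which can be old. Of the other 32539 probe sets, 15495 had 1 gene symbol, 279 had several and 16765 had none here, and only those with 1 symbol were named. Gene IDs of 15384 probe sets matched the reference gene table for assembly Xenopus_laevis_v10.1, which changed the symbol of 2. No genome build is named in the sources used here, and no coordinates are given. Homeologs and other near-identical copies can share probes, and probe sets designed on one homeolog may also bind the other.

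Values under 1 were set to 1 and log2 was taken with no offset. Probe sets in the lowest 40% by mean log2 intensity over all 6 arrays (mean intensity under 6.94) were left out, which left 19523. The highest intensity among 59 unspiked control probe sets was 4.1 to 6.7 per array. A gene at or under that level on all 3 arrays of a group was treated as having only a bound there, and its fold was computed against the higher of its own value and that level on each array, as were those of *grip2.L* and *pcsk6.L*, which passed that level on only some animal arrays, a rule set after seeing the control values. Arrays give no count of molecules, and their number limits the precision.

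Animal and vegetal samples were compared with limma (version 3.58.1, R 4.3.3), by lmFit and eBayes with a mean-variance trend, two-sided, with Benjamini-Hochberg adjustment over the probe sets tested and a threshold of 0.05. All 6 arrays entered the fit, with no block. Where a gene had several probe sets, the one with the highest mean log2 intensity stood for it. Among genes with several tested probe sets, 124 had probe sets past the threshold in opposite directions. Lists of genes were fixed before the data were examined, and homeologs were counted as separate members. The lists were germ plasm RNAs, vegetal cortex RNAs, reported animal RNAs, the Wnt and TGF-beta pathways, RNA-binding proteins, cell cycle, ribosomal proteins, respiratory chain, mitochondrial genome, histones, proteasome, cytoskeleton, membrane traffic, glycolysis, genes of the later embryo, and follicle and blood markers. They overlap in a few genes, such as *wnt11b.L*, *gdf1.S*, *dand5.S* and *tdrd6.L*. Each of the 15 lists with at least 2 tested members was tested with camera at a preset correlation of 0.01, adjusted over the 15 lists, with an estimated correlation and fry beside it. With an estimated correlation none of the 3 lists called with the preset one passed. The estimates were 0.43 for the germ plasm, 0.54 for the vegetal cortex and 0.00023 for the Wnt list. The last lies under the preset 0.01, so a higher correlation between its genes did not end that call. With an estimated correlation camera also takes its degrees of freedom from the arrays, which are few. By fry, which tests whether a list's genes move one way on balance and does not compare them with other genes, 12 of the 15 lists passed, so that fry does not set the 3 lists apart.

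The genes named were chosen by a rule written before the data were examined: in each direction the 10 genes with the largest log2 difference among those past the threshold with non-overlapping groups and an informative symbol, all tested members of the 3 lists of localized RNAs, and up to 4 members of each other list. Correlations of same-numbered replicates' deviations from their group means were between -0.023 and 0.0063, so same-numbered replicates did not deviate together. That cannot show whether they shared embryos, which the labels do not say.

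The fit was tested on simulated values for the 19523 probe sets with the real means and spreads and 50 probe sets changed at each size. It recovered 32% of changes of 1.41-fold, 58% of 2-fold, 92% of 4-fold and 96% of 8-fold, and 4.79% of its calls were false. Far fewer probe sets were changed there than the 10195 called in the data. With fewer true changes the adjustment is stricter, so these shares hold for the simulated setting and not for the real comparison. Alternatives were quantile and median scaling, no filter or a filter at 60%, an offset at the 20th percentile (1.6), no trend, robust estimation, the replicate number as a block, leaving out each array, leaving out probe sets that can bind several transcripts and averaging a gene's probe sets. An offset of 16, scaling to the 27 spiked controls and the Wnt list without *wnt11b* were added after seeing the data. Figures were drawn with matplotlib 3.10.9.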

Results

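RNA was measured on 6 one-colour oligonucleotide arrays from *Xenopus laevis* embryos at the 8-cell stage, before the embryo's own genome is active, so that nearly all messenger RNA in the samples had been laid down in the egg. The animal group held 3 samples of animal blastomeres, the upper tier of cells. The vegetal group held 3 samples of the vegetal-most part of the vegetal blastomeres, whose equatorial part had been cut away and discarded to widen the contrast. The comparison asked which maternal RNAs are enriched at the animal pole. Each array gave 1 scaled intensity for each of 32539 probe sets other than controls, of which 15495 could be assigned to 1 gene. Symbols end in .L or .S for the 2 copies (homeologs) that most genes have in this allotetraploid frog. All array means below are intensities ± SD with n = 3, and all fold values come from differences of mean log2 intensity with 95% confidence intervals. The labels do not say whether replicates came from separate clutches, so p-values measure only the spread between these samples.

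Arrays of one group were more alike than arrays of different groups. Over the tested probe sets, Pearson's r between log2 intensities was 0.987 for each pair of animal arrays, 0.981 to 0.983 between vegetal arrays and 0.889 to 0.895 between an animal and a vegetal array. Control probe sets for the 3' and 5' parts of *gapdh*, a glycolytic enzyme, gave a 3' to 5' ratio of 4.18 ± 0.19 (SD, n = 3) in animal and 7.35 ± 0.41 (SD, n = 3) in vegetal samples. The ratio of the 3' to the middle part of cytoplasmic actin was 7.42 ± 0.47 (SD, n = 3) in animal and 13.1 ± 1.5 (SD, n = 3) in vegetal samples. Its 3' to 5' ratio was 183 ± 79 (SD, n = 3) in animal and 324 ± 43 (SD, n = 3) in vegetal samples. The groups did not overlap for any of these ratios (two-sided exact permutation p = 0.1 for each, the smallest that 3 arrays against 3 allow). For the 3' to middle ratio of *gapdh* they did, at 2.16 ± 0.25 (SD, n = 3) in animal and 2.74 ± 0.39 (SD, n = 3) in vegetal samples (exact permutation p = 0.2). Bacterial and phage RNAs spiked into the hybridization read 1404 ± 140 (SD, n = 3) on animal and 1660 ± 182 (SD, n = 3) on vegetal arrays, with overlap between groups (exact permutation p = 0.2).

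**Figure D1:**
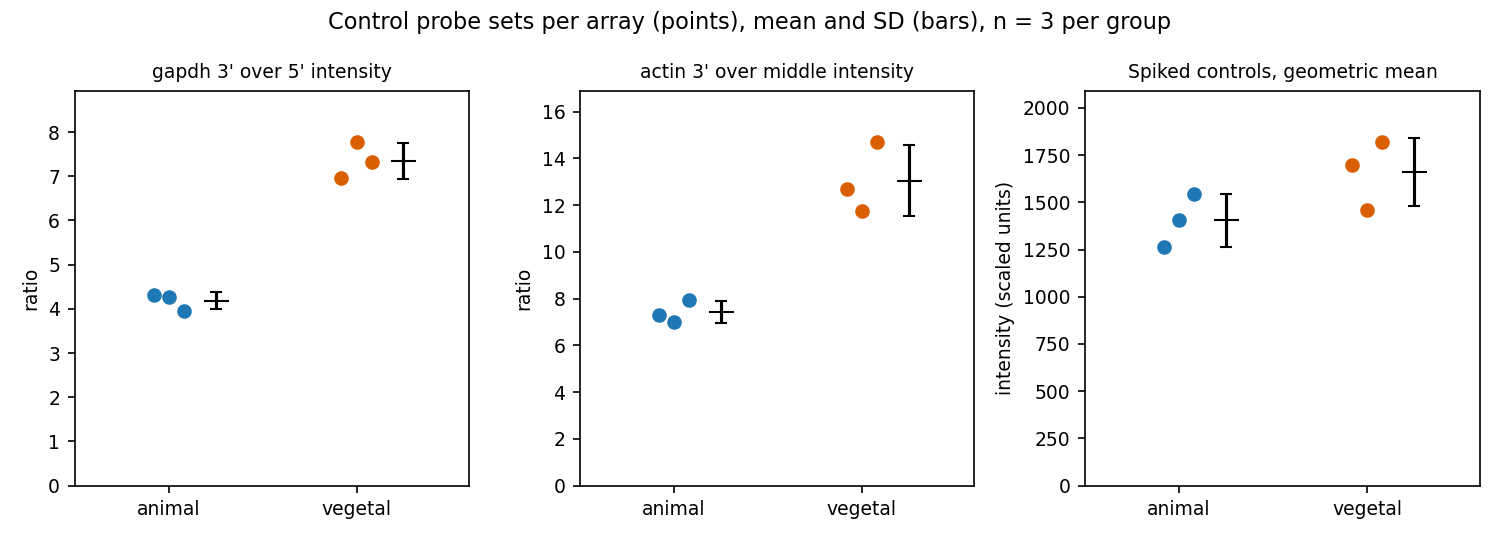
Control signals on each array (points) with the group mean and SD (bars, n = 3): the *gapdh* 3' to 5' intensity ratio, the actin 3' to middle intensity ratio, and the geometric mean intensity of the spiked controls, each on an axis from 0. Both ratios are higher on every vegetal array than on any animal array, with means of 7.35 against 4.18 and 13.1 against 7.42.

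Relative RNA levels differed between the animal and vegetal samples for many probe sets. Of 19523 probe sets tested, 6188 were higher in animal and 4007 were higher in vegetal samples at an adjusted p under 0.05 (limma moderated test with Benjamini-Hochberg adjustment). At 2-fold or more, 2263 were higher in animal and 1415 in vegetal samples. Counted by gene, with 1 probe set for each of 8026 genes, 2177 genes were higher in animal and 1905 in vegetal samples, of which 638 and 527 differed by at least 2-fold. The values of the 2 groups did not overlap for 58.3% of genes, against 10% by chance. The direction of the larger share depended on the scaling of the arrays: animal-higher calls made up 60.7% of all calls as deposited, 54.0% after quantile normalization, 35.6% after centring on array medians and 79.5% after scaling to the spiked controls. The median difference over all tested probe sets moved with it, from 0.12 (log2, animal minus vegetal) as deposited to -0.15 after median centring, so that small differences are relative to the scaling.

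Germ plasm RNAs, a list fixed before the data were examined, made up 7 of the 10 vegetal genes that the fixed rule named. The rule orders fitted log2 differences of 1 probe set per gene, leaves out locus-type names and takes in genes with only a bound, so the 10 are not a measured ranking. *grip2.L*, which encodes a scaffold protein with PDZ domains, read 4.57 ± 2.80 (SD, n = 3) in animal and 3029 ± 432 (SD, n = 3) in vegetal samples, at least 543-fold higher in vegetal samples (limma adjusted p = 1.98e-12), with 1 of the 3 animal arrays above the unspiked controls. Its other probe sets were at -10.001 and -5.16 (log2, animal minus vegetal). Their mean log2 animal signals were under the highest unspiked controls, so these values are not measured sizes. *germes.L* was 254-fold higher in vegetal samples (184 to 351), and *nanos1.L*, a translational repressor of the germ line, was 235-fold higher (183 to 302). *pgat.L* was 199-fold higher (164 to 240), *sybu.S*, which encodes the kinesin linker syntabulin, 87.2-fold (72.2 to 105), *dazl.L*, a germ line RNA-binding protein, 63.1-fold (53.1 to 74.9), and *rtn3.S*, a reticulon of the endoplasmic reticulum, 63.0-fold (49.4 to 80.4). The other 3 of the 10 were *pcsk6.L*, *six3.L* and *ank1.S*. *pcsk6.L* encodes a proprotein convertase that cleaves TGF-beta family precursors and was at least 52.4-fold higher in vegetal samples, with 2 of the 3 animal arrays above the controls. Its other probe set was at -6.73 (log2), which is not a measured size, since its mean log2 animal signal was under the highest unspiked controls. *six3.L*, a homeobox gene, and *ank1.S*, an ankyrin, were not above the unspiked control probe sets on any animal array and were at least 15.99-fold and at least 29.6-fold higher in vegetal samples. Such bounds are set against the highest unspiked control on each array.

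Of 14 tested genes in the germ plasm list, 13 were higher in vegetal samples, all by at least 2-fold, and 1 was higher in animal samples (the same counts adjusted over the list alone). The list's median difference was -5.93 (log2), and -5.97 relative to all genes (limma camera with a preset correlation, adjusted p = 1.41e-16; adjusted p = 0.18 with an estimated correlation). *wnt11b.L*, a Wnt ligand of the dorsal pathway, was 59.3-fold higher in vegetal samples (49.4 to 71.2), and *ddx25.L*, a DEAD-box helicase, 24.2-fold (20.6 to 28.3). Differences were smaller for *dnd1.L*, an RNA-binding protein of germ cells, which read 1227 ± 28 (SD, n = 3) in animal and 4411 ± 607 (SD, n = 3) in vegetal samples, 3.57-fold (3.13 to 4.08). *rbpms2.S* and *rbpms2.L* (Hermes) were 3.78-fold and 2.52-fold higher in vegetal samples, and *rtn3.L* was 3.43-fold higher by its brightest probe set and 5.57-fold and 7.65-fold by its others. The exception was *tdrd6.L*, a Tudor-domain protein, at 87.3 ± 8.4 (SD, n = 3) in animal and 63.0 ± 2.4 (SD, n = 3) in vegetal samples, 1.38-fold higher in animal samples (limma adjusted p = 0.0178). That call was lost without animal replicate 1 (limma adjusted p = 0.082), after quantile normalization (0.0901) and after median centring (0.278).

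Maternal RNAs reported on the vegetal cortex outside the germ plasm class behaved alike in direction. Of 14 tested, 13 were higher in vegetal samples, each by at least 2-fold, and 1 was higher in animal samples (the same counts adjusted over the list alone), with a list median of -2.999 (limma camera adjusted p = 1.15e-14; adjusted p = 0.20 with an estimated correlation). *trim36.L*, a ubiquitin ligase, was 37.0-fold higher in vegetal samples (30.1 to 45.6) and *gdf1.S* (Vg1, a TGF-beta family ligand) 35.2-fold (28.96 to 42.8), with 122.7 ± 28.8 (SD, n = 3) in animal and 4262 ± 443 (SD, n = 3) in vegetal samples. The homeobox gene *otx1.L* was 19.9-fold, the ephrin *efnb1.L* 15.4-fold, the actin nucleator *spire1.S* 13.5-fold, and the RNA-binding repressors *bicc1.L* and *bicc1.S* 12.1-fold and 11.7-fold higher in vegetal samples. *vegt.L* and *vegt.S*, T-box activators of endoderm, were 4.61-fold and 3.87-fold higher, *velo1.L* 5.44-fold, *sox7.L* 4.87-fold, and the lipid droplet genes *plin2.S* and *plin2.L* 2.90-fold and 2.82-fold. Of the other probe sets of *plin2.L*, one was at -1.85 and one was higher in animal samples, at 0.53 (log2, limma adjusted p = 0.000687). *hook2.L* was 1.35-fold higher in animal samples (limma adjusted p = 0.000447), a call that ended after median centring (0.128).

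**Figure D2:**
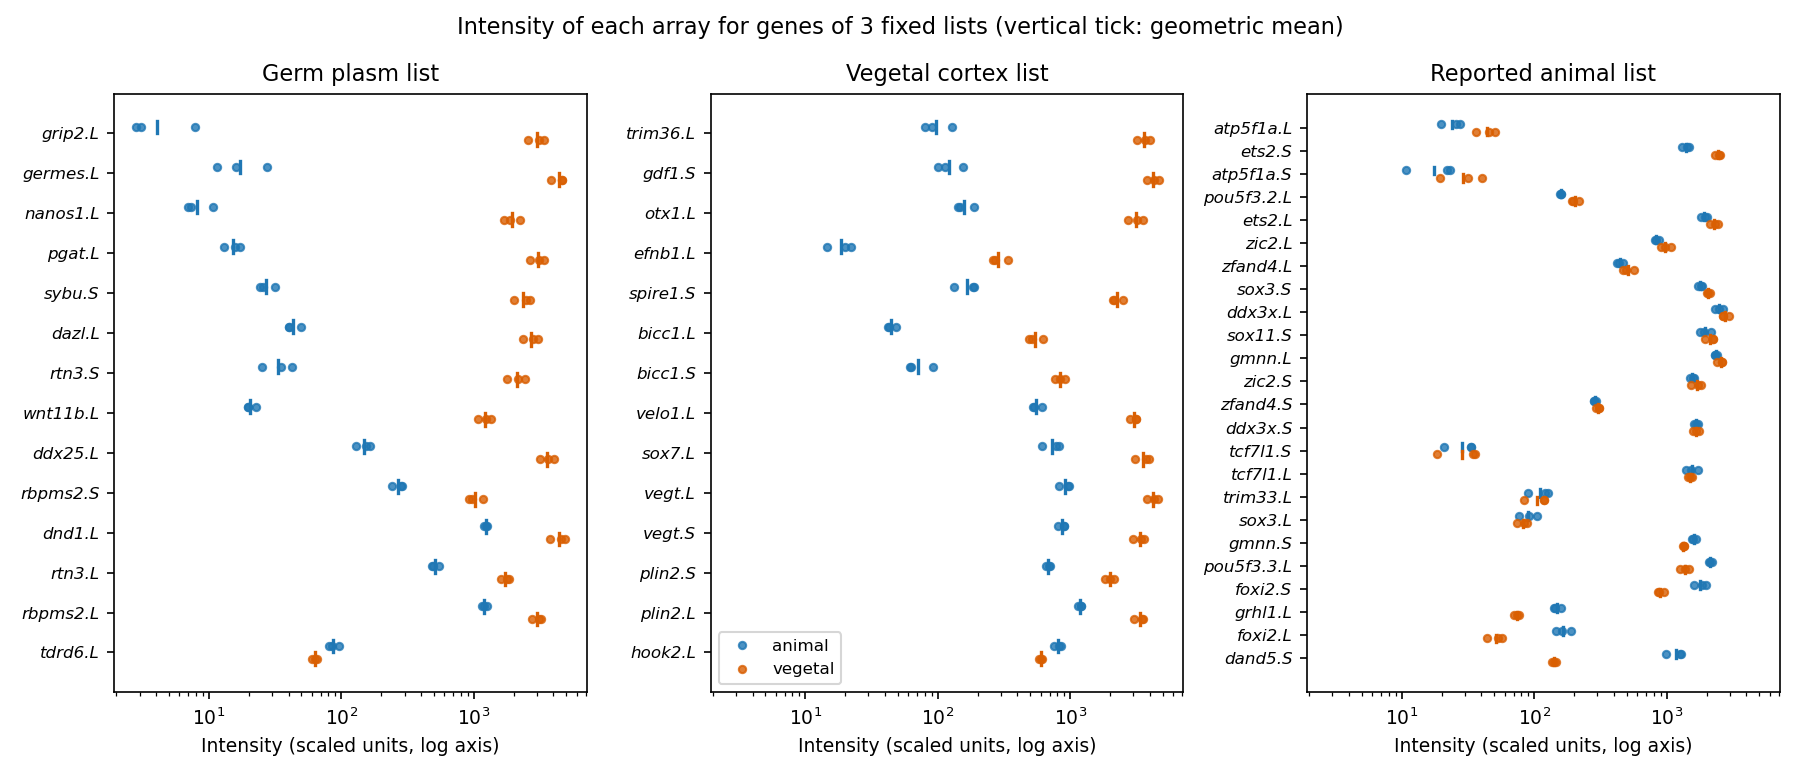
Intensity (scaled units, log axis) on each of the 3 animal and 3 vegetal arrays (points) for every tested gene of 3 fixed lists, with the geometric mean of each group as a vertical tick. In the germ plasm and vegetal cortex lists all genes but *tdrd6.L* and *hook2.L* lie higher on every vegetal array, whereas most genes of the reported animal list lie close together in the groups and *dand5.S* stands apart, with arithmetic means of 1176 against 141.

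The reported animal RNAs did not shift past the threshold relative to other genes. Of 24 tested, 6 were higher in animal samples, 6 were higher in vegetal samples and 12 did not pass (the same counts adjusted over the list alone). The list's median was -0.09 and its mean 0.15, with an upward camera statistic that did not pass (limma camera adjusted p = 0.92), whereas the test against no change, which does not compare the list with other genes, did (limma fry adjusted p = 0.00381). The largest difference was in *dand5.S* (Coco, a secreted antagonist of nodal and BMP signals), at 1176 ± 168 (SD, n = 3) in animal and 141 ± 4 (SD, n = 3) in vegetal samples, 8.29-fold higher in animal samples (7.07 to 9.70, limma adjusted p = 8.22e-12), and 3.13-fold higher by its other, dimmer probe set. *foxi2.L* and *foxi2.S*, forkhead activators of ectoderm, were 3.199-fold (2.54 to 4.04) and 2.00-fold (1.76 to 2.28) higher, *grhl1.L*, an epidermal transcription factor, 2.01-fold (1.65 to 2.44) and *pou5f3.3.L* 1.55-fold (1.39 to 1.74). *gmnn.S* (geminin) was 1.2-fold higher in animal samples as deposited and at -0.0057 (log2) after median centring. *atp5f1a.L*, *ets2.S*, *ets2.L*, *pou5f3.2.L*, *zic2.L* and *sox3.S* were higher in vegetal samples by 1.148-fold to 1.82-fold. The other probe sets of *ets2.S* did not pass (limma adjusted p = 0.637 and 0.716). The calls of *zic2.L* and *sox3.S* turned to small animal differences under spiked-control scaling. Those of *atp5f1a.L*, *pou5f3.2.L* and *ets2.L* ended there (limma adjusted p = 0.0574, 0.688 and 0.963). Without single arrays the call of *zic2.L* ended 4 times (limma adjusted p = 0.1 without animal replicate 2, 0.0964 without animal replicate 3, 0.0646 without vegetal replicate 2 and 0.134 without vegetal replicate 3). That of *sox3.S* ended 3 times (limma adjusted p = 0.0646 without animal replicate 2, 0.0909 without animal replicate 3 and 0.0788 without vegetal replicate 1), and that of *ets2.L* without vegetal replicate 3 (limma adjusted p = 0.0521). All 3 calls also ended after quantile normalization (limma adjusted p = 0.0656 for *zic2.L*, 0.567 for *sox3.S* and 0.213 for *ets2.L*) and without the mean-variance trend (0.118, 0.108 and 0.0812). That of *zic2.L* ended with no filter on low values (limma adjusted p = 0.0853) and with the replicate block (0.0561) as well. After median centring 5 members were higher in animal and 14 in vegetal samples, and after spiked-control scaling 7 and 1.

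The 10 animal genes that the same rule named were not members of the germ plasm, vegetal cortex or reported animal lists. Of these, 8 were not above the unspiked controls on any vegetal array, so that only a lower bound holds and their order is not a measured one. *fut10.L*, a fucosyltransferase, read 200 ± 18 (SD, n = 3) in animal samples and was at least 35.3-fold higher there. *evl.S*, an actin regulator of the Ena/VASP family, was at least 23.1-fold higher, *tyw3.L*, a tRNA-modifying enzyme, at least 22.8-fold, *chrng.L*, an acetylcholine receptor subunit, at least 21.9-fold, and *nr3c1.S*, the glucocorticoid receptor, at least 18.1-fold. *acot2.S*, an acyl-CoA thioesterase, was at least 16.1-fold, *urod.S*, an enzyme of haem synthesis, at least 10.6-fold and *tbxas1.L*, thromboxane synthase, at least 10.03-fold higher in animal samples. *slc7a8.L*, an amino acid transporter, read 242 ± 5 (SD, n = 3) in animal and 4.77 ± 3.41 (SD, n = 3) in vegetal samples, where 1 of the 3 arrays was above the controls. The tenth, *pfn1.L* (profilin, an actin-binding protein), was above the unspiked controls on every array, at 820 ± 99 (SD, n = 3) in animal and 33.6 ± 5.7 (SD, n = 3) in vegetal samples, 24.5-fold higher in animal samples (19.9 to 30.2, limma adjusted p = 2.41e-12). Each of these 10 genes was represented by a single tested probe set. Whether the higher 3' to 5' control ratios of the vegetal samples went with a lower vegetal signal of these probe sets was not tested.

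**Figure D3:**
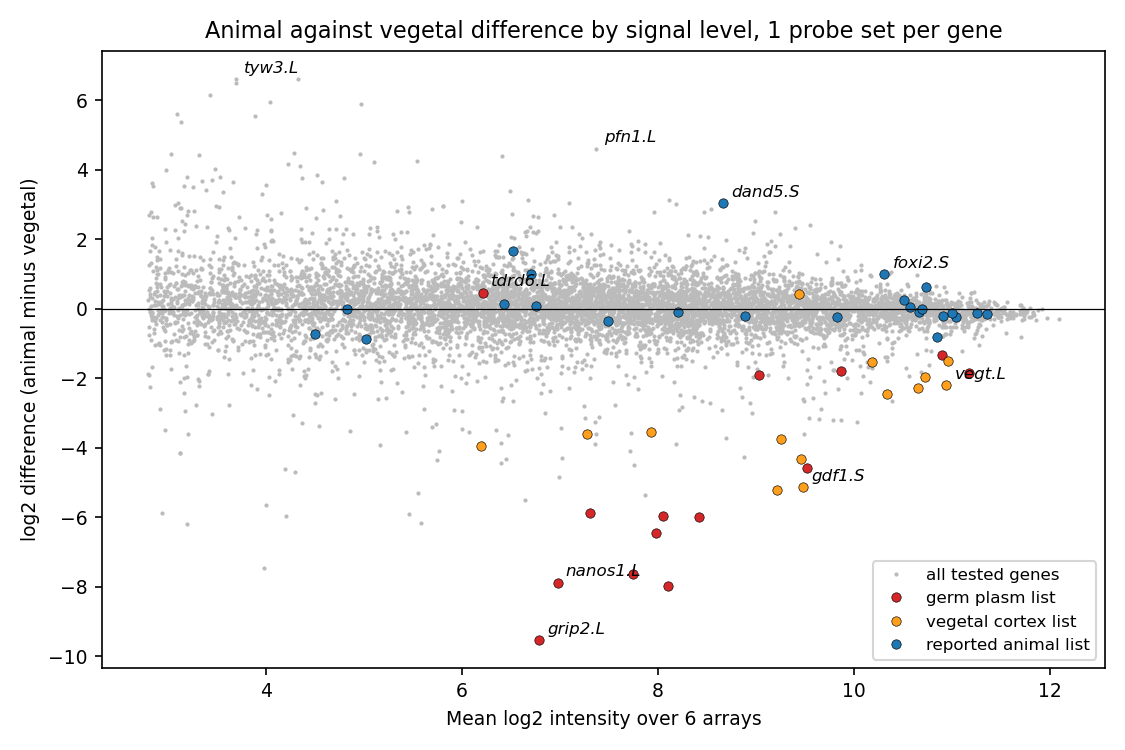
Difference of mean log2 intensity (animal minus vegetal) against mean log2 intensity over the 6 arrays, 1 point per tested gene (8026 genes), with 3 fixed lists in colour. Germ plasm genes such as *nanos1.L* at -7.88 lie far below the other genes of their level. Many of the points highest in the plot are genes at low mean intensity whose vegetal signal was not above the unspiked controls, so that their height is no measured size.

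Components of the TGF-beta pathway were split between the poles, and more Wnt components were higher in vegetal than in animal samples. Over all 8026 tested genes 2177 were higher in animal and 1905 in vegetal samples. Calls in both directions are therefore not particular to these lists or to those below. In the TGF-beta list 13 of 42 tested genes were higher in animal, 13 were higher in vegetal samples and 16 did not pass (the same counts adjusted over the list alone). The list median was 0.02 and the mean -0.13, and the list did not shift past the threshold as a whole (limma camera adjusted p = 0.81). Its counts turned with the scaling, to 7 and 18 after median centring and 17 and 8 under spiked-control scaling. Beside *gdf1.S*, *pcsk6.L* and *dand5.S*, *bmp2.L*, a BMP ligand, was 8.28-fold higher in animal samples (6.85 to 10.01) by its brightest probe set and 1.62-fold by the other (limma adjusted p = 0.000563). In the Wnt list 17 of 40 tested genes were higher in vegetal and 3 in animal samples, and 20 did not pass (the same counts adjusted over the list alone), with a median of -0.20 as deposited and 0.04 under spiked-control scaling. After median centring 24 were higher in vegetal and 0 in animal samples, and under spiked-control scaling 9 and 6. The shift relative to all genes passed with a preset correlation (limma camera adjusted p = 0.00849; adjusted p = 0.18 with an estimated correlation) and without *wnt11b* (0.0258, an alternative chosen after seeing the data), but not after quantile normalization (0.0908) or with the mean of all probe sets of a gene (0.0837). Its members included *btrc.L*, a ubiquitin ligase component that targets beta-catenin, 2.63-fold higher in vegetal samples (2.17 to 3.18; 1.65-fold by its other probe set). Another, *tcf7l2.L*, a transcription factor of the pathway, was 2.00-fold higher in vegetal samples (1.61 to 2.48) by its brightest probe set. Its other tested probe sets were at -0.15 and -0.52 (log2) and did not pass (limma adjusted p = 0.79 and 0.26). The mean over all its probe sets, with those below the intensity filter included, was at -0.17 (log2, limma adjusted p = 0.735).

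RNA-binding proteins of RNA localization and maternal translation went both ways, as did the tested genes at large. Of 55 tested, 13 were higher in animal and 17 in vegetal samples, or 13 and 18 adjusted over the list alone (limma camera adjusted p = 0.50), with 5 and 30 after median centring and 20 and 7 under spiked-control scaling. *ptbp1.L*, a polypyrimidine tract-binding protein that binds localized vegetal RNAs, was 8.73-fold higher in animal samples (7.01 to 10.9), and 2.04-fold higher by its other, dimmer probe set. *zfp36l2.L*, a CCCH zinc finger protein that promotes RNA decay, was 4.52-fold higher in vegetal samples (3.73 to 5.48), and *ddx6.L*, a helicase of repressed RNA particles, 2.91-fold (2.33 to 3.63). *zfp36.L* was not above the controls on any animal array and was at least 5.35-fold higher in vegetal samples.

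Among cell cycle genes, 17 of 72 tested were higher in animal and 26 in vegetal samples, or 17 and 27 adjusted over the list alone (limma camera adjusted p = 0.29), with 9 and 45 after median centring and 22 and 10 under spiked-control scaling. *cdc25a.S*, a phosphatase that activates cyclin-dependent kinases, read 48.1 ± 10.5 (SD, n = 3) in animal and 579 ± 42 (SD, n = 3) in vegetal samples, 12.2-fold higher (9.79 to 15.2). *chek1.S*, the checkpoint kinase that acts on CDC25 phosphatases, was 3.39-fold higher in vegetal samples (2.95 to 3.91), and 2.69-fold by its other probe set. Both homeologs of the mitotic kinase *aurka* were higher in animal samples, *aurka.S* by 6.87-fold (5.70 to 8.29) and *aurka.L* by 3.80-fold (2.69 to 5.39).

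Housekeeping groups did not pass as lists, and the order of the 2 counts turned with the scaling in each of them. For ribosomal proteins 19 of 84 tested genes were higher in animal and 11 in vegetal samples (17 and 10 adjusted over the list alone; limma camera adjusted p = 0.72), with 5 and 32 after median centring and 32 and 3 under spiked-control scaling. *rps4x.S* was 2.51-fold and *rpl34.L* 2.14-fold higher in animal samples, and *rpl29.L* 2.04-fold and *rps6.L* 1.85-fold higher in vegetal samples. For nuclear-encoded respiratory chain subunits 16 of 77 were higher in animal and 19 in vegetal samples (14 and 17 adjusted over the list alone; limma camera adjusted p = 0.71), with 5 and 33 after median centring and 21 and 5 under spiked-control scaling. *ndufa6.S* was 4.43-fold higher in animal samples and *cox7c.S* 2.61-fold higher in vegetal samples. For proteasome subunits 18 of 55 were higher in animal and 4 in vegetal samples (17 and 4 adjusted over the list alone; limma camera adjusted p = 0.29), with *psmc3.S* 4.47-fold and *psma6.L* 2.75-fold higher in animal samples. The proteasome counts were 10 and 12 after median centring and 22 and 0 under spiked-control scaling. The cytoskeletal list had 23 of 76 higher in animal and 11 in vegetal samples (the same counts adjusted over the list alone, limma camera adjusted p = 0.50). In it *pfn1.L* was 24.5-fold higher in animal and *actn1.L*, alpha-actinin, 2.63-fold higher in vegetal samples. The other probe set of *actn1.L* gave 3.78-fold. Its mean log2 animal signal was under the highest unspiked controls, so that fold is not a measured size. The membrane traffic list had 39 of 136 higher in animal and 25 in vegetal samples (37 and 25 adjusted over the list alone; limma camera adjusted p = 0.71), with *vamp8.S* 5.90-fold and *arl9.L* 4.82-fold higher in vegetal samples. *rab36.L* was higher in animal samples, at 19.3 ± 6.7 (SD, n = 3) against 5.77 ± 6.001 (SD, n = 3), with overlapping groups and 1 of the 3 vegetal arrays above the controls (limma adjusted p = 0.0109). That call ended with no filter on low values (limma adjusted p = 0.164), without the mean-variance trend (0.0739) and without animal replicate 3 (0.05). After median centring the counts were 12 and 25 for the cytoskeletal list and 23 and 50 for the membrane traffic list, and under spiked-control scaling 28 and 6 and 53 and 11.

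For glycolytic enzymes 3 of 18 were higher in animal and 6 in vegetal samples (the same counts adjusted over the list alone), with a median of -0.26 and counts of 2 and 9 after quantile normalization, 0 and 12 after median centring and 3 and 4 under spiked-control scaling (limma camera adjusted p = 0.22). Both homeologs of *pgam1*, phosphoglycerate mutase, were higher in vegetal samples, *pgam1.L* by 5.38-fold (4.71 to 6.14) and *pgam1.S* by 3.09-fold (2.70 to 3.53). Among histones 2 of 13 were higher in animal and 2 in vegetal samples (1 and 2 adjusted over the list alone), with a median of -0.08, a mean of 0.01 and a downward camera statistic (limma camera adjusted p = 0.90), and with 1 and 6 after median centring and 5 and 0 under spiked-control scaling. The linker histone *h1-10.S* was 2.13-fold higher in animal samples (1.89 to 2.40) by its brightest probe set, whereas its other probe set was 1.35-fold higher in vegetal samples (limma adjusted p = 0.0264). The egg linker histone *h1-8.S* was 1.24-fold higher in vegetal samples, a call that ended under spiked-control scaling (limma adjusted p = 0.608). Histone genes are near copies of one another, and their probe sets may not separate them.

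Genes listed as markers of later or other cells mostly fell below the intensity filter. Of 44 genes of the list transcribed after the midblastula stage, 43 fell below the intensity filter. The other one, the secreted protein gene *szl.S*, read 11.03 ± 2.14 (SD, n = 3) in animal and 24.0 ± 7.6 (SD, n = 3) in vegetal samples (limma adjusted p = 0.00976, and 0.0542 without vegetal replicate 3 and 0.0582 with no filter on low values). Of 23 genes listed as markers of ovarian follicle cells and blood, 21 fell below the filter. Whether the RNA of the other 2 came from such cells or from the egg itself was not tested. *cyp17a1.L*, a steroid-synthesis enzyme, read 634 ± 13 (SD, n = 3) in animal and 2027 ± 141 (SD, n = 3) in vegetal samples, 3.19-fold higher in vegetal samples (2.85 to 3.58; 2.59-fold by its other probe set). A haemoglobin gene, *hba-l5.L*, read 349 ± 27 (SD, n = 3) and 316 ± 26 (SD, n = 3) and did not pass (limma adjusted p = 0.233), although its other probe set did, at 0.38 (log2, limma adjusted p = 0.034). With 1 of the 2 tested members past the threshold, also over the list alone, that list did not pass (limma camera adjusted p = 0.36). No probe set was assigned to a gene of the mitochondrial genome, so that list was not analysed here.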

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

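The offset of 16, the spiked-control scaling and the Wnt list without *wnt11b* were chosen after the results were seen, and the other alternatives before the data were examined. The 2-fold vegetal count, 1415 as deposited, stayed between 1374 and 1451 without any single array, and the other counts ranged over 5318 to 5894 (higher in animal), 3496 to 3835 (higher in vegetal) and 2149 to 2392 (animal, 2-fold). Median centring moved 3 counts by over 1.5 times, to 3682 higher in animal, 6661 higher in vegetal and 1466 animal at 2-fold, since it shifts every difference towards the vegetal side by the same amount. Leaving out the lowest 60% of probe sets gave 1074 animal and 877 vegetal 2-fold calls, with fewer probe sets tested. An offset of 16 gave 1235 animal 2-fold calls, since it shrinks the folds of dim probe sets, and spiked-control scaling gave 1980 vegetal calls and 3461 animal 2-fold calls. At 2-fold the animal share was 61.5% as deposited, 49.9% after quantile normalization, 41.4% after median centring and 76.7% under spiked-control scaling. The germ plasm and vegetal cortex shifts kept their direction and stayed past the threshold in the 17 alternatives run for lists with the preset correlation, at -6.07 to -5.27 and -3.11 to -2.79 relative to all genes, but not with an estimated correlation (adjusted p = 0.18 and 0.20). Not all of these could have changed a list result. The fits with no trend and with robust estimation do not alter the list test, so they repeat it. Median and spiked-control scaling move all genes of an array alike, so they keep the shift relative to all genes by construction. Leaving out probe sets that can bind several transcripts was run for counts only. The Wnt shift, -0.23, was -0.13 after quantile normalization and -0.24 with the mean of all probe sets, past the threshold in neither (the cause was not tested), and -0.25 to -0.16 without single arrays. The other 12 tested lists passed in none. Same-numbered samples did not deviate together, and the replicate block gave 6017 animal and 3858 vegetal calls (2274 and 1413 at 2-fold) and ended the calls of *zic2.L* (limma adjusted p = 0.0561) and *h2az1.L* (0.0705) among the named genes. Among values of named genes under the alternatives, 1711 stayed on their side of the threshold (28 of these, in 12 genes, changed sign with no call on either side), 59 lost and 12 gained the call, and 5 changed sign with a call on at least one side: after median centring *ddx3x.S* was at -0.27, *gmnn.S* at -0.0057 and *h2az1.L* at -0.041, and after spiked-control scaling *zic2.L* was at 0.014 and *sox3.S* at 0.041. The *gapdh* ratio difference (animal minus vegetal), -3.17, was -3.37 to -2.96 without single arrays. The mean correlation between groups, 0.892, was 0.943 with no filter, where dim probe sets enter. Some genes had no value under the stricter filter. Signal near the unspiked controls limits the folds of dim genes.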

Other observations

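Of the tests below, the one on the scaling of the arrays and the one with 1 value per gene were chosen after the result was seen, and the random draws at matched levels were added after the difference between dim and bright probe sets, though not their own outcome, had been seen. Over 1357 pairs with both copies tested, the log2 differences of .L and .S copies had a Pearson's r of 0.24 and a Spearman's rho of 0.25 across genes, which are not independent replicates. Both copies were called in the same direction in 291 pairs and in opposite directions in 121, with both copies at 2-fold or more in 38 of the former and 6 of the latter. One of these 6 was *bmp2*, with *bmp2.L* 8.28-fold higher in animal samples and *bmp2.S* at 567 in animal and 1192 in vegetal samples, although the other probe set of *bmp2.L*, at 0.69 (log2), is under 2-fold. Others, named after their values were seen, were *txndc12* (-1.53 for .L, or -0.68 by its other probe set, and 3.76 for .S, log2, animal minus vegetal), *pkp3* (-2.00 and 1.59) and *exd2* (1.196 and -1.65). If copies were paired at random, 165 to 206 opposite pairs would be found (central 95% of 1000 pairings matched on level), so the observed 121 argue against copies that are independent of each other. Probes shared between copies could also make pairs more alike, and were not tested.

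More probe sets were higher by at least 2-fold in animal than in vegetal samples, and this excess was larger in dimmer probe sets. In the dimmest 4881 of the tested probe sets (mean intensity 6.94 to 27.9) 918 were higher in animal and 417 in vegetal samples at 2-fold, against 681 and 381 in the next 4881, 486 and 338 in the next 4880, and 178 and 279 in the brightest 4881 (336 to 7419), and the median difference went from 0.27 over 0.20 and 0.12 to -0.0059. Whether the deposited scaling sets the balance cannot be told apart from a true excess: the animal share of 2-fold calls was at most 49.9% under quantile and median scaling, which centre the arrays and so bear on the balance by construction, and 76.7% under spiked-control scaling. Shorter labelled fragments in the vegetal samples stay open too: in 1692 genes with 2 or more probe sets, the dimmest lay above the brightest by a median of 0.16 (bootstrap interval 0.13 to 0.20), as loss of signal far from the 3' end would give, but by 0.041 (0.013 to 0.072) after quantile normalization, which itself removes shifts that follow level. Random pairs of different genes at the same levels gave a median of 0.12 (0.070 to 0.17 in 200 draws), so a dependence on signal level common to all probe sets accounts for the values too, and a larger set of RNAs kept in animal cells stays open.

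Genes over 8-fold higher in animal samples rested mostly on single probe sets. Of 47 such genes, 7 had another tested probe set, and these 8 probe sets had a median difference of 1.01 (interval 0.39 to 4.69), 6 called higher in animal samples and none in vegetal. With 1 value per gene the median was 1.03 (0.69 to 4.69) with 3 of 7 genes under 2-fold, and since both medians pass 2-fold by less than their spread, it stays open whether the difference belongs to 1 probe set or to the gene's RNA. Of 73 genes over 8-fold higher in vegetal samples, 13 had other probe sets, and these 24 had a median of -3.03 (-3.50 to -0.82), 17 called in the same direction and none opposite, but 9 of the 24 belong to 1 gene, and with 1 value per gene the median was -2.79 (-3.45 to -0.19) with 6 of 13 genes under 2-fold, so this stays open for the vegetal genes as well. The 8 animal values ran from 0.33 and 0.39 (both *chaf1b.L*, not past the threshold) over 0.69 (*bmp2.L*), 0.995 (*xylt1.L*), 1.03 (*ptbp1.L*) and 1.65 (*dand5.S*) to 4.69 (*runx1.L*) and 5.28 (*rgs4.S*), of which *chaf1b.L*, *xylt1.L*, *runx1.L* and *rgs4.S* were named after their values were seen.

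Other splits of the 6 samples into 3 and 3 number 10 with the real one, too few for a share under 0.05. The real split called 10195 probe sets, 3678 of them at 2-fold, and each of the other 9 called 0 at both (limma), with 117 to 272 probe sets at an unadjusted p under 0.05 against 11219 for the real split. Only the real one, 1 of the 10, gave as many. Each other split has animal and vegetal arrays on both sides, so the difference between poles widens the spread within its groups. Few calls would follow from that alone, so these splits do not show how many calls arise by chance. For gene lists the real split called 3 and the highest other split 5, and 9 of 10 splits called at least 3. The other splits divide the animal arrays unevenly and so keep part of the difference between poles. Their list calls therefore do not show how many lists chance would call.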
